A study of Arabidopsis thaliana with 12 samples.

How the data were processed

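The samples came from roots and shoots of Arabidopsis thaliana seedlings aged 4 days, with 3 ribosome profiling and 3 RNA-seq samples per tissue by the labels. Per the submitters' processing notes, the genome build was TAIR10 and the tools named were Bowtie2 and STAR 2.5.1b, with no role or order. The ORF caller, and how the 3 samples of a tissue entered its ORF set, are not given in the sources used here. The deposited count per ORF is a whole number, with a minimum of 6 in each tissue, given once per ORF and repeated on each exon block. The unit was read from the values, as the tables have no header. Among ORFs of a gene that lie inside another, 3320 pairs in root and 3303 in shoot, the inner ORF never had the larger count, and the count was read as the number of ribosome P sites or footprints in the ORF. It was not scaled by length or depth. The count per replicate was not analysed here, so each tissue has 1 value per ORF. RNA-seq values were not analysed here, and no translational efficiency was computed.

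Each row set with the same name was joined into 1 ORF with its category and blocks, and the coding length was taken from the transcript positions in the name. Block sums differed from that length by 1 base in all 21768 root and 21128 shoot ORFs, so outer ends are uncertain by 1 base. Starts are given 1-based in the TAIR10 coordinates of the tables. Gene symbols came from the locus tags of a RefSeq table (assembly TAIR10.1), used for names only. Of 18273 gene identifiers, 18135 matched a locus tag. The 67 plastid identifiers were each named by the 1 plastid gene they lie in, within 2 bases. All 231 entries of the 16 gene lists matched.

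A gene counted as translated in a tissue when it had at least 1 ORF of any category there. ORFs counted as identical when strand and all block coordinates matched. For overlap by bases, bedtools 2.31.1 was used with strand. Because nested ORFs share counts, gene values use the largest ORF count of the gene. These summed to 113381941 in root and 95481490 in shoot, the sums used for scaling. Ratios are log2 of shoot over root shares with a pseudocount of 0.5, for genes with at least 100 counts in the higher tissue. The design set this ratio per ORF. That it would be taken from the longest coding ORF with identical coordinates in both tissues, and that 4-fold would be the size counted, was settled after the data were seen.

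Shares carry exact binomial (Clopper-Pearson) and counts exact Poisson 95% intervals, which cover counting error only. Sequenced fragments without molecular identifiers are not independent molecules, and differences between plants are not included. No test between tissues was made, as there is 1 set for each. Each gene list was set against 10000 random lists of the same size, drawn within 10 bins of count, as a description of these 2 sets. The net number of shoot-only minus root-only genes and the median log2 ratio were compared in this way. In percentiles, ties count at 50%.

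Before the data were examined, the lists, the rule for named genes and the alternatives were fixed. The rule took, per list and in list order, up to 4 genes found in 1 tissue only for each tissue and up to 2 found in both. It also took the 8 genes with the largest count of each tissue only, the 5 longest shared and 3 longest one-tissue uORFs and ORFs of non-coding genes, the 3 largest length differences in each direction, and the 10 highest and 10 lowest ratios. Other genes named are marked as chosen after their values were seen. The values of 1 gene that the rule takes are not reported here.

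The alternatives were coding ORFs only, at least 20 or 100 codons, ORF counts of at least 627 (the first quartile over both sets), nuclear chromosomes only, matching by stop codon, by reciprocal overlap of 50% or by 1 base, genes in place of ORFs, 1 ORF per gene, a pseudocount of 5, scaling on the median ratio and no count filter. The largest ORF of each gene in place of the identical ORF was added after the data were seen, as was the conserved-uORF list without SAC51. Alternatives that need values per replicate were not run.

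The ratio step was tested on simulated root and shoot counts, drawn from Poisson distributions around the real means with 200 genes changed. All 50 genes changed 2-fold, 100 changed 4-fold and 50 changed 8-fold had the right sign, and 0 of 14442 unchanged genes passed 4-fold. The changed genes had means of at least 100, and the largest count per gene was used in place of the identical ORF. As only counting error was simulated, the result checks the computation. It says nothing about differences between plants, libraries or ORF calls. The matching step found 300 of 300 simulated identical ORFs, which were copies of unspliced ORFs, so matching of spliced ORFs was not simulated. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.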

Results

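The data described here came from ribosome profiling of roots and shoots of Arabidopsis thaliana seedlings aged 4 days. Ribosome profiling sequences the short RNA fragments that ribosomes protect, and so shows which open reading frames (ORFs) are being translated. The series held 12 samples in 4 groups, with 3 ribosome profiling and 3 RNA-seq samples for each tissue. The ORF tables used here held 1 set of translated ORFs for root and 1 for shoot, with 1 whole-number count per ORF. RNA-seq values were not analysed here, so translation was not separated from transcript level. As each tissue had 1 set, with no value per replicate, no comparison below has a replicate check and no p-value is given. Intervals cover counting error only.

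The root set listed 21768 ORFs and the shoot set 21128. After ORFs with the same coordinates were merged, 21673 ORFs of 16757 genes remained in root and 21038 ORFs of 16191 genes in shoot. The largest ORF counts of the genes summed to 113381941 in root, over 7635950 codons, a mean of 14.8 counts per codon. In shoot the sum was 95481490 over 7401597 codons, a mean of 12.9. These sums cover called ORFs only and are not the depth of the libraries. PYK10 (AT3G09260), a beta-glucosidase of endoplasmic reticulum bodies, had the largest root count, 1719622, or 1.52% of the root sum (the genes of this paragraph were chosen after their values were seen). ATMS1 (AT5G17920), a methionine synthase, followed with 1021326. In shoot the largest count was 1120539 for rbcL (ATCG00490), the plastid-encoded large subunit of Rubisco, or 1.17% of the shoot sum. RBCS1A (AT1G67090), a small subunit of Rubisco, followed with 1065418. The 10 genes with the largest counts held 5.61% of the sum in root and 6.96% in shoot.

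The first comparison asked which genes had a translated ORF in each tissue. The genes with the largest counts in root only included HRGP1 (AT3G54590), a hydroxyproline-rich glycoprotein, and AGP30 (AT2G33790), an arabinogalactan protein. Those in shoot only included the plastid genes psbA, psbD, psbC, petA and petD. Of 18273 genes with an ORF in either tissue, 14675 were found in both (80.3%, exact binomial 95% interval 79.7 to 80.9). Another 2082 genes were found in root only (11.4%, 10.9 to 11.9) and 1516 in shoot only (8.30%, 7.90 to 8.71). The sets list only ORFs that were called, so a gene missing from a tissue was not shown to be untranslated there, and no fold was computed for it.

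Among the genes of root only, HRGP1 had the largest count, 87005 (Poisson 95% interval 86428 to 87585), on chromosome 3 from 20206224 to 20208471. AT4G12545 followed with 65512, AGP30 with 32889, AT3G55750 with 29048, AT1G23720 with 28967, AT3G23510 with 23980, AT4G33120 with 21754 and the cytochrome P450 gene CYP705A12 (AT5G42580) with 21622. Among the genes of shoot only, psbA (ATCG00020), which encodes the D1 protein of photosystem II, had the largest count, 200090 (199214 to 200969), on the plastid chromosome from 386 to 1443. psbD (ATCG00270), for the D2 protein, had 118340 counts and psbC (ATCG00280), for the CP43 antenna protein, 106442. petA (ATCG00540) and petD (ATCG00730) of the cytochrome b6f complex had 38801 and 29053, and atpH (ATCG00140) of the ATP synthase had 28490. The nuclear genes among the 8 with the largest counts were NIT2 (AT3G44300), a nitrilase, with 42081 counts and TUB2 (AT5G62690), a beta-tubulin, with 40098. Genes of one tissue only had lower counts than shared genes. Their median was 497 in root and 418 in shoot, against 2244 and 1627 for the shared genes.

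The gene lists set before the data were examined placed stomatal genes on the shoot side and root hair genes on the root side. Of 13 genes of stomatal development, 11 were found in shoot only, 2 in both and 0 in root only. The transcription factors SPCH (579 counts), MUTE (228) and FAMA (878) and the receptor-like protein TMM (3919) were among the 11. ICE1 and SCRM2 were found in both tissues, with 973 and 276 root counts and 2986 and 3132 shoot counts. The excess of 11 genes on the shoot side lay at percentile 100 of 10000 random lists matched on count, whose 95% range was -4 to 3. Of 16 genes of the shoot meristem and leaf polarity, 5 were found in shoot only, 6 in both and 5 in neither. AS1 (1025 counts), FIL (2058), YAB3 (1366) and TCP4 (413), which are leaf development genes, stood in shoot only, and the list lay at percentile 99.975 of the random lists.

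Of 19 root hair genes, 5 were found in root only, 13 in both and 0 in shoot only. The basic helix-loop-helix factors RHD6 (1523 counts) and RSL4 (7314), the expansin EXPA18 (15188) and MRH6 (4599) stood in root only. The list lay at percentile 0.015 of the random lists, whose range was -3 to 2. Of 11 root meristem and auxin transport genes, 3 stood in root only, namely the meristem factors PLT1 (621 counts) and PLT2 (538) and the root cap factor SMB (394), and the list lay at percentile 1.89. Its net number, -3, was at the edge of the random range of -3 to 2. Of 19 nutrient uptake genes, HKT1 (704) and SULTR1;1 (2459) stood in root only, at percentile 4.12, and 15 were found in both. The net number of -2 was also at the edge of its random range, -2 to 2. All 11 genes of the endodermis and its Casparian strip were listed in both tissues, as were all 12 clock genes, all 12 photosystem I genes and all 11 photosystem II genes. The 6 cuticular wax genes were also listed in both, as were 13 of 14 housekeeping genes, 14 of 16 Calvin cycle genes and 15 of 16 chlorophyll synthesis genes. In the light-harvesting antenna list, 16 of 20 genes stood in both, LHCA6 in shoot only with 5567 counts and LHCB1.1 (AT1G29920) in root only with 14426. LHCB1.1 belongs to a family of near-identical copies, so its placement is uncertain, as is that of other close copies such as TUB2. When ORF counts of at least 627 were required, the number of shoot-only minus root-only genes went from 11 to 7 for stomata, from -5 to -9 for root hairs, from 0 to -7 for the endodermis, from -2 to -8 for nutrient uptake and from -3 to -1 for the root meristem list, whose 3 root-only genes had lower counts.

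**Figure D1:**
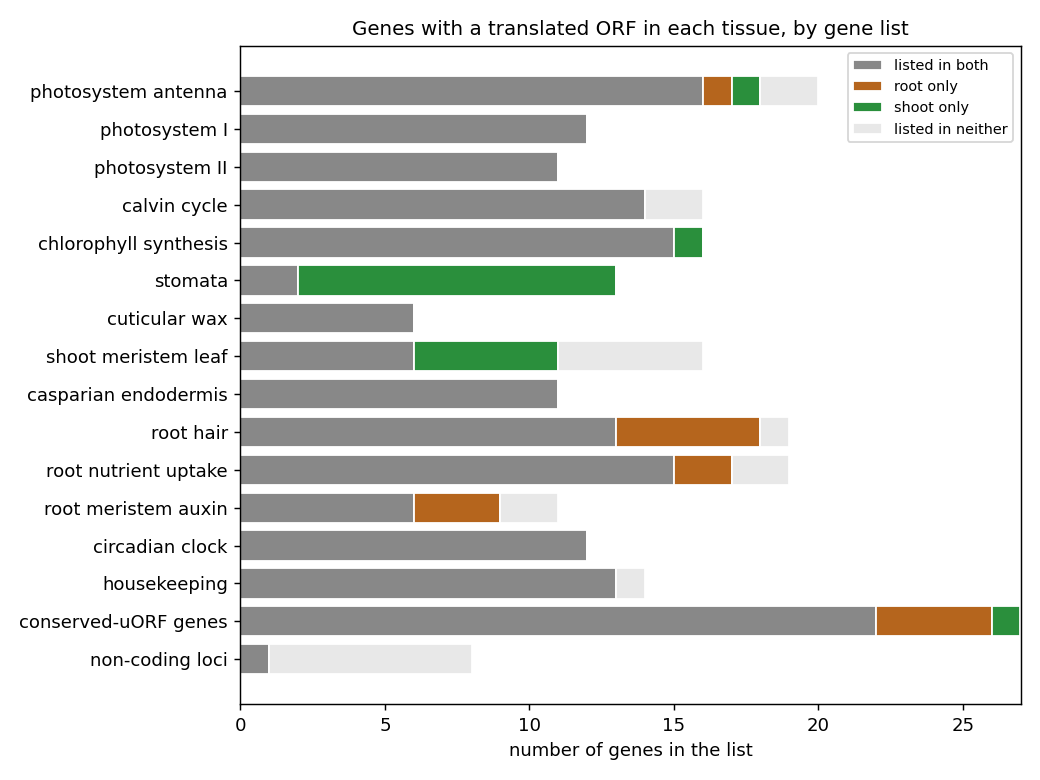
Horizontal bars count the genes of each list with a translated ORF in both tissues, root only, shoot only or neither. The stomata bar holds 11 shoot-only genes of 13 and the root hair bar 5 root-only genes of 19.

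The counts per ORF were compared next, for the longest coding ORF with identical coordinates in both tissues of each gene. Most photosynthesis genes had shares of the shoot total many times their shares of the root total, and most root hair and endodermal genes the opposite. Of 11581 genes with at least 100 counts in the higher tissue, 1016 were at least 4-fold higher in shoot and 960 at least 4-fold higher in root. Ratios are of shares of each tissue's sum, with a pseudocount of 0.5. The median log2 ratio of shoot over root was -0.33, so that scaling on the median ratio would move every gene by that amount and give 1194 and 730 genes instead, or 62.1% on the shoot side in place of 51.4%. With the largest ORF of each gene, identical or not, 1397 of 14659 genes were higher in shoot and 1450 in root, or 49.1% on the shoot side.

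The genes of photosynthesis were higher in shoot without exception among those with an identical ORF. The median log2 ratio was 4.74 for 14 antenna genes, 4.82 for 12 photosystem I genes, 4.41 for 11 photosystem II genes, 5.11 for 12 Calvin cycle genes and 4.47 for 12 chlorophyll synthesis genes. Each of the 5 medians lay at percentile 100 of 10000 random lists matched on count. LHCA1, an antenna protein of photosystem I, had 6525 root and 176900 shoot counts (32.2-fold) and LHCA2 had 6862 and 151216 (26.2-fold). PSAD1 was 27.4-fold and PSAD2 37.8-fold higher in shoot. The oxygen-evolving complex genes PSBO1 and PSBO2 were 18.4-fold and 15.9-fold higher. In the Calvin cycle, RBCS1A was 46.2-fold higher over an ORF of 57 codons, and RBCS2B, which had no identical ORF, had largest counts of 10867 in root and 411569 in shoot. TIM, a triose phosphate isomerase chosen after its value was seen, was the lowest of this list at 3.20-fold. HEMA1, at the start of chlorophyll synthesis, was 13.4-fold higher and GSA1 3.98-fold. PORA, a protochlorophyllide oxidoreductase, stood in shoot only with 1011 counts. Over the 61 genes of these lists, the root share was a median of 3.82% of the shoot share, with quartiles of 2.94% and 5.43% and a range of 1.76% to 31.2%.

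Genes of the cuticular wax list with an identical ORF were also higher in shoot, with a median log2 ratio of 3.33 over 4 genes (percentile 99.9). CER1 was 12.5-fold and CER3 8.03-fold higher. CER4, chosen after its value was seen, went the other way, with largest ORF counts of 11350 in root and 165 in shoot. The 4 shoot meristem and leaf genes with an identical ORF had a median of 0.49 (percentile 88.2). ICE1, the 1 stomatal gene with an identical ORF, was 3.64-fold higher in shoot. KNAT1, a homeobox gene, was 4.23-fold higher in shoot, and CLV1, a receptor kinase, had largest counts of 3174 in root and 3895 in shoot.

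Among root lists, 10 root hair genes had a median log2 ratio of -5.37 and 6 endodermal genes -3.92, both at percentile 0 of the random lists. The expansin EXPA7 was 48.6-fold higher in root, with 17572 against 304 counts, and COW1 16.1-fold. CASP1 and CASP2, membrane proteins of the Casparian strip, had no identical ORF. Their largest counts were 19925 and 6827 in root and 380 and 52 in shoot. SCR, chosen after its value was seen, was the endodermal gene closest to equal shares, at -0.16, and its sign flips when ratios are scaled on the median gene. EGL3 of the root hair list, also chosen after its value was seen, had no identical ORF and went the other way, with largest counts of 475 in root and 861 in shoot. The 11 nutrient uptake genes had a median of -1.87 (percentile 0.02). The nitrate transporter NRT1.1 was 2.62-fold and NRT3.1 4.47-fold higher in root. Root meristem and auxin transport genes went both ways, with a median of 0.61 over 3 genes (percentile 91.0), which became -0.43 over 6 genes with the largest ORF of each gene. PIN2 had largest counts of 13324 in root and 169 in shoot.

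The circadian clock list had a median of -0.30 over 8 genes (percentile 51.3), with 4 genes above 0 and 4 below, and the sign of the median flips to 0.04 with median scaling. The morning genes CCA1 and LHY were 6.24-fold and 4.35-fold higher in shoot. ELF4 and GI, chosen after their values were seen, were 54.8-fold and 4.90-fold higher in root. Of the remaining clock genes with an identical ORF, also named after their values were seen, RVE8 (log2 ratio 2.02) and ZTL (0.59) were higher in shoot. LUX (-1.98) and TOC1 (-1.18) were higher in root. The median of this list therefore hides genes far from 0 in both directions. The hour at which each tissue was collected was not examined here. Whether it differed and bears on this split or on the other lists was not tested. The housekeeping list had a median of -0.55 over 13 genes (percentile 23.7). Of the 13, 11 lay below 0 and 9 below the median of all genes. The actins ACT2 and ACT7 were 2.47-fold and 1.52-fold higher in root.

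**Figure D2:**
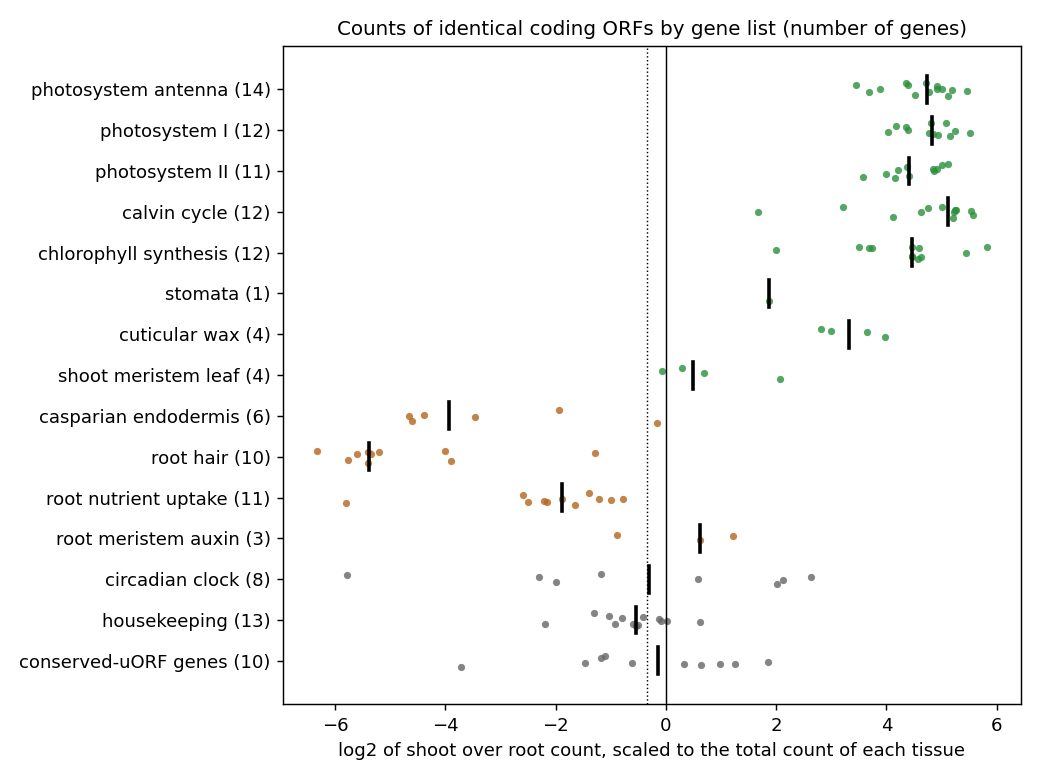
Each point is a gene, placed on the log2 ratio of its shoot over root count, with a bar at the median of each list and a dotted line at the median of all genes, -0.33. The photosynthesis lists lie between 1.68 and 5.82, and 9 of the 10 root hair genes are at least 4-fold higher in root.

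The lowest single ratio was that of UMAMIT4 (AT3G18200, chromosome 3 from 6234512 to 6236058), of a family of amino acid transporters, with 5637 counts in root and 7 in shoot (2.81 to 14.4), a log2 ratio of -9.31, or -8.63 with a pseudocount of 5. AT5G24880 had 4217 and 7 counts (-8.89, or -8.21 with that pseudocount) and AT5G55110 3568 and 9 (-8.31). The next were AT5G47980 (-7.12), AT1G52070 (-7.04), its neighbour AT1G52060 (-6.96), AT5G54370 (-6.91), SHV2 (-6.90), which acts in root hair growth, the MADS-box gene AGL12 (-6.87) and AT3G19430 (-6.85). The highest was LDOX (AT4G22880, chromosome 4 from 12004908 to 12006058), an enzyme of anthocyanin synthesis, with 674 root and 45401 shoot counts, a ratio of 6.32. ESM1 (6.17) and the myrosinase TGG2 (6.07) of glucosinolate breakdown followed, then the carbonic anhydrase CA1 (6.06), AT3G47650 (6.03), PnsB1 of the chloroplast NDH complex (5.95), CA2 (5.89), the lipoxygenase LOX2 (5.88), CRR41 (5.83) and PORB (5.82).

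**Figure D3:**
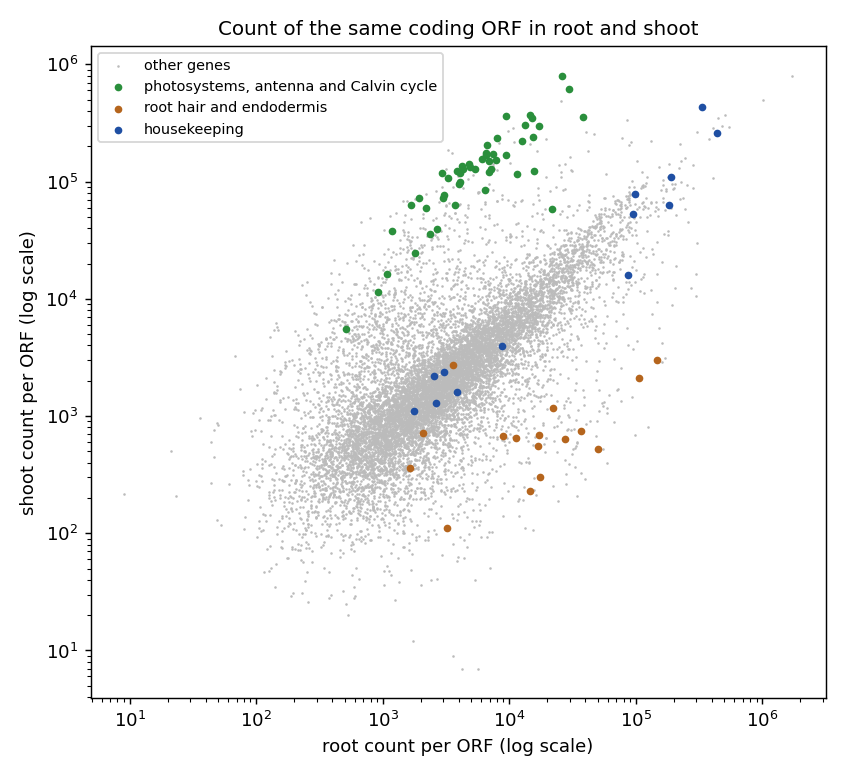
Each point is a coding ORF with identical coordinates in both tissues, with its root count on the horizontal and its shoot count on the vertical log axis. Photosynthesis genes such as LHCA1 (6525 root, 176900 shoot) lie above the bulk and root hair genes such as EXPA7 (17572 root, 304 shoot) below it.

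The ORFs were then compared by category. Annotated coding ORFs made up 21482 of the root ORFs (99.1%, 99.0 to 99.2) and 20895 of the shoot ORFs (99.3%, 99.2 to 99.4). Upstream ORFs (uORFs), which lie in the 5' leader of a coding gene, numbered 108 in root (0.498%, 0.409 to 0.601) and 66 in shoot (0.314%, 0.243 to 0.399). ORFs in genes annotated as non-coding numbered 81 in root and 69 in shoot. Downstream ORFs numbered 2 in root, in AT1G52300 and the root hair gene PRP3, and 7 in shoot, which also listed 1 downstream ORF overlapping the coding ORF, in AT5G38360. The downstream ORF genes were named after their values were seen. Coding ORFs had a median of 374 codons in both tissues, with quartiles of 236 and 554 in root and 238 and 555 in shoot. They had a median of 5 exon blocks, and 84.7% in root and 85.5% in shoot spanned more than 1 block. uORFs had medians of 22 and 21.5 codons, and those of non-coding genes 148 and 235.

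Coordinates of 14898 ORFs were identical in both tissues, 68.7% of the root ORFs (68.1 to 69.4) and 70.8% of the shoot ORFs (70.2 to 71.4). The share differed by category. Of coding ORFs in root, 69.1% (68.5 to 69.8) were identical in shoot, against 14.8% (8.71 to 22.9) of uORFs and 34.6% (24.3 to 46.0) of ORFs in non-coding genes. None of the 2 root downstream ORFs was listed in shoot. The categories also differed in count. Median counts were 221.5 in root and 137.5 in shoot for uORFs, and 444 and 365 for ORFs in non-coding genes. For coding ORFs they were 1879.5 and 1473. An ORF missing from a tissue was not shown to be untranslated there, and the shares were not compared at equal counts.

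For uORFs, the longest shared one was an ORF of 119 codons of AT3G24070 on chromosome 3 from 8693173 to 8693530, with 365 root and 132 shoot counts. The next longest shared uORFs were those of AT5G17460 (73 codons, 6598 and 422 counts), AT1G67480 (72 codons, 855 and 465), the polyamine oxidase PAO4 (50 codons, 3757 and 800) and OTLD1 (43 codons, 500 and 253). In root only, the longest were in AT4G22120 (84 codons), AT1G03370 (79) and the protein kinase CIPK15 (63). In shoot only, they were in PSBP-2 (123 codons, 125 counts), GAUT14 (54) and AT2G44770 (53). uORFs were listed for 103 genes in root and 64 in shoot, of which 20 were common to both. Among genes with a coding ORF in both tissues, 14 of 100 root uORFs were identical to one of 61 shoot uORFs. Outer ends of listed ORFs are uncertain by 1 base, because block lengths and coding lengths differed by 1.

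Of 27 genes known for conserved uORFs, 22 were listed in both tissues, 4 in root only and 1 in shoot only, at percentile 25.4 of the random lists. bZIP11 (698 counts), bZIP44 (880), bZIP53 (1289) and SACL2 (227) stood in root only and SACL1 (117) in shoot only. The longest coding ORF listed for SACL1 had 54 codons, and whether it is the main ORF of the gene was not checked. bZIP2 and bZIP1 had 1669 and 264 largest counts in root and 79 and 138 in shoot. Neither had an identical ORF, so these counts are of different ORFs. The longest ORF was listed in root only for bZIP2, SAC51, SACL3, TPPF, LHW, WNK5 and PIA1. It was listed in shoot only for bZIP1 and CRF12 (genes other than bZIP2 and bZIP1 were named after their values were seen). That these genes were listed in both tissues therefore does not place their longest ORF in both. The median log2 ratio of the 10 with an identical ORF was -0.14 (percentile 71.7), or 0.19 with median scaling. One of the 10 is SAC51, whose identical ORF of 53 codons lies upstream of its main ORF, and the median of the other 9 was 0.34. Conserved uORFs often have gene identifiers of their own and count as coding ORFs, so ORFs under 100 codons within 2000 bases upstream were also sought, a search chosen after the data were seen. One was found in root for 9 of the 27 genes and in shoot for 6. For SAMDC1, an enzyme of polyamine synthesis, the upstream ORF of 52 codons had 13796 root and 6903 shoot counts, and the main ORF 9716 and 10158. SAMDC1 had no coding ORF with identical coordinates in both tissues, so the main ORF counts may be of different ORFs. With 366 codons taken for the main ORF in both tissues, the upstream ORF had 9.99 times its count per codon in root and 4.78 times in shoot. For the homeobox gene HB1 these values were 1.83 and 3.09, and for EIF5 0.805 and 0.898.

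Transposable elements gave the longest ORFs in genes annotated as non-coding. The longest in both tissues was that of AT2G06950, with 1402 codons on chromosome 2 from 2859229 to 2863433, 1550 root and 2079 shoot counts. AT3G43955 followed (1372 codons, 1700 and 2907 counts), then AT1G80020 (1070 codons, 7439 and 6115), AT5G55896 (1037 codons, 2454 and 1242) and MUG7 (767 codons, 5588 and 2949). In root only, the longest were in AT5G44925 (1449 codons, 133 counts), MUG6 (716, 1702) and CYTOSLEEPER (706, 300). In shoot only, they were in AT2G23330 (1496 codons, 46 counts), AT1G10160 (854, 21) and CYTOSLEEPER (799, 508), whose root and shoot ORFs had the same stop codon and differed in length. MUG6 and CYTOSLEEPER had a listed ORF in both tissues, so the tissue given is that of the ORF and not of the gene. Transposable elements held 31 of 81 such ORFs in root and 40 of 69 in shoot, pseudogenes 27 and 14, and non-coding RNA genes 22 and 13. Of 8 well-known non-coding loci, TAS3 was listed in both tissues, with 997 root and 598 shoot counts, and 7 were listed in neither (percentile 53.4).

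The last comparison asked whether a gene was represented by the same coding ORFs in both tissues. Of 14635 genes with a coding ORF in both, 3729 had different sets (25.5%, 24.8 to 26.2). When only different stop codons were counted, the number was 341. In 69.9% of the 3183 genes whose longest ORFs shared a stop codon but not a start, the shorter ORF was in the tissue with fewer counts per codon. AT5G15070 had the largest excess in root, with a longest ORF of 1059 codons (926 counts) against 70 in shoot (147 counts). AT1G26130 had 1185 and 433 codons and AT3G50010 751 and 108. AT5G46450 had the largest excess in shoot, with 1123 codons (2171 counts) against 210 in root (9 counts). AT5G15280 had 974 and 73 codons, and psaA (ATCG00350), a reaction centre protein of photosystem I, 750 codons with 139149 counts in shoot and 18 codons with 353 counts in root, ending at another stop codon.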

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

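No paired analysis was possible because each tissue has 1 ORF set and its count column carries no replicate number. The replicate block, leaving out replicates and other size factors per replicate were not run for the same reason. The use of the largest ORF per gene and the median without SAC51 were chosen after the data were seen. Of 1976 genes with a ratio of at least 4-fold, 0 changed direction with the largest ORF. This is a weak check, as the largest ORF is often the identical one. Of 150 single genes, 145 stayed within their counting interval with it. Some medians close to 0 changed sign: median scaling moved the clock list from -0.30 to 0.04 and the conserved-uORF list from -0.14 to 0.19, leaving out SAC51 moved the latter to 0.34, and the largest ORF moved the root meristem list from 0.61 to -0.43; the cause was not tested. The numbers of genes in both tissues, in root only and in shoot only stayed within 1.5 times the reported values under all 5 alternatives, the furthest being 10215 and 2921 genes with ORF counts of at least 627 for both tissues and root only, and 1431 with at least 100 codons for shoot only. Root ORFs found in shoot rose from 14898 to between 18862 and 19212 under looser matching. With at least 20 codons, uORFs numbered 58 in root and 37 in shoot. Counting different stop codons only left 341 genes with different coding ORFs. The longest ORF of each gene had a median of 390 codons in root and in shoot. The largest ORF of each gene gave 1450 genes of 14659 at least 4-fold higher in root, against 960 of 11581, and the cause was not tested. Scaling on the median ratio moved the medians to 5.07 for the antenna, 5.16 for photosystem I, 5.44 for the Calvin cycle and 4.81 for chlorophyll synthesis. It did so by construction, as every ratio moves by the same amount. With ORF counts of at least 627, the shoot-only minus root-only number was 7 for stomatal and -9 for root hair genes. It was -7 for endodermal, -8 for nutrient uptake and -8 for conserved-uORF genes, which had 0, -2 and -3, and went from -3 to -1 for root meristem genes. Such changes follow from the cut, which takes a gene out of a tissue where its largest count is under 627. In shoot, CASP1 to CASP5, ESB1 and MYB36 had largest counts of 52 to 559. In root, PLT1, PLT2 and SMB had 621, 538 and 394. No ORF in these sets had an overlapping uORF class, so counting it in changed nothing. Of 150 single genes, 150 stayed within their counting interval with a pseudocount of 5 and 7 with median scaling. Low shoot counts limit the folds of genes such as UMAMIT4, with 7 counts and a log2 ratio of -9.31, or -8.63 with a pseudocount of 5.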

Other observations

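Tests chosen only after the result was seen were those on the gene families, on root hair and endodermis genes called in shoot, on plastid-encoded ORFs identical in both tissues and on genes over 2 times or under 50% of a median share. Gene families not described above were taken by symbol from the reference names. Proteins of the plastid transcription machinery (PTAC) were higher in shoot, with a median log2 ratio of 3.31 over 11 genes (percentile 100 of 10000 matched random lists), from 0.94 for PTAC9 to 5.37 for PTAC16. Glutathione transferases of the GSTU class had a median of -1.58 over 13 genes (percentile 0.01), with GSTU22 at -3.98 and GSTU16 at 4.13. The WRKY, MYB and NAC transcription factor families leaned to root, with medians of -1.12 for 22 WRKY genes (percentile 0.17), -1.12 for 19 MYB genes (0.74) and -0.90 for 26 NAC genes (1.22). In the same families 13 WRKY, 21 MYB and 10 NAC genes were found in root only, against 2, 9 and 2 in shoot only. The median of 61 genes with a CYP symbol was -1.05 (percentile 0). They were taken as cytochrome P450 genes, but the highest, CYP38 at 4.76, is a cyclophilin. The CYP set is therefore mixed, and its values are not those of cytochrome P450 genes alone. The WRKY, MYB, NAC, CYP and GSTU medians also lay below the median of all genes, -0.33. B-box factors had 8 genes in shoot only, 8 in both and 0 in root only. UGT, XTH, EXPA, AGP, PIP, ABCG, BBX and UMAMIT medians lay between percentiles 7.41 and 72.4.

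Plastid-encoded ORFs were listed for 67 genes in shoot and 14 in root, all 14 of them also in shoot. They held 2.79% of the shoot sum and 0.0470% of the root sum. Of the 7 with an identical ORF, accD, for a subunit of acetyl-CoA carboxylase, had nearly equal counts of 4163 in root and 4054 in shoot (log2 ratio 0.21). The protease subunit gene clpP had 2.12, rpl14 2.80, rps2 3.60, atpB 3.36 and psbB 3.69. rbcL was listed in root by an ORF of 3 codons with 572 counts, against 479 codons and 1120539 counts in shoot.

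Genes called in one tissue only had low counts, and a count close to the calling floor is a candidate explanation for their absence from the other tissue. It did not account for all of them. Of root-only genes, 12.2% (10.9 to 13.7) had a count at or above the median of shared genes, and of shoot-only genes 19.7% (17.7 to 21.7), where under 5% was expected if the floor were the cause and 10% or more if not. Reads shared between near-identical copies, as for LHCB1.1 and TUB2, and a true difference between the tissues stay open as untested.

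Coding ORFs with the same stop codon and different starts were found as the longest ORF of 3183 genes, shorter in shoot for 1737 and in root for 1446, with a median difference of 34 codons. In 69.9% of them (68.3 to 71.5) the shorter ORF was in the tissue with fewer counts per codon. Lower coverage may therefore shorten the called ORF in many of these genes. A choice of start or transcript that differs between tissues remains open as untested.

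Photosynthesis genes called in root could come from shoot tissue carried over. For 61 nuclear genes, the root share was a median of 3.82% of the shoot share. The upper quartile was 1.85 times the lower, under the bound of 2 set for carry-over beforehand. Translation in root at a similar share for all these genes would also pass it, so the bound cannot tell the 2 apart. One even share did not account for all, as 6 of the 61 genes, TIM, GSA1, PGK1, LHCB1.5, CHLG and PSBR, lay over 2 times the median by more than counting error. Reads of LHCB1.5 may be shared with near-identical copies, as for LHCB1.1, so its share is uncertain. In the other direction 9 genes, from LDOX at 1.25% to PORB at 1.76%, lay under 50% of that median by more than counting error. The bound of 10 genes for excluding a share at the median was set after the result was seen, so falling short decides nothing. An even share could not be larger than the shares of these 9 genes. Genes listed in shoot only had no root share and did not enter. All 7 plastid-encoded ORFs identical in both tissues lay over 2 times the nuclear median, from 7.77% for psbB, close to that limit, to 86.5% for accD, but they are those also called in root, and the root share of all plastid counts was 1.69% of the shoot share with 53 plastid genes not listed in root. A smaller or uneven carry-over and translation in root stay open. Root hair and endodermis genes called in shoot had quartiles 3.11 times apart over 16 genes, and shares from 1.25% to 89.5% of the root share. An even carry-over of root tissue did not account for them, as 4 genes, SCR, GL2, MYB36 and GSO1, lay over 2 times the median by more than counting error, and 32 genes of all those compared, UMAMIT4 among them, lay under 50% of it. Carry-over of only a part of the root and translation in shoot stay open as untested.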
